A study of Rattus norvegicus with 12 samples.

How the data were processed

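Gene expression was measured on 12 one-colour Agilent rat arrays, 3 each for DMSO, triclosan, diclosan and CCPB, in cryopreserved primary hepatocytes of male Sprague Dawley rats exposed at 30 µM for 24 h after 24 h of culture. Per the labels, RNA was extracted with a miRNeasy kit and labelled with Cy3 by the Low Input Quick Amp method. Groups were taken from the sample labels, and no column of another sample was present (0).

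Per the file headers, the deposited scanner files hold the intensity of each spot, made by the authors with Agilent Feature Extraction 10.7.1.1. This intensity is linear, background-subtracted and detrended within the array, with a floor for dim spots and without scaling between arrays. The authors' deposited value table holds a linear signal per probe in which the 75th percentile of each array is 1 (0.9995 to 1, medians 0.048 to 0.055), with 0 zeros. It correlated with the scanner values at 0.999999 on each array, so the scanner intensity was used, with the table as an alternative. Spot flags for signal well above background, non-uniformity, population outliers and saturation were read from the same files. Detrending and the floor compress differences between dim spots, and scaling to a percentile assumes that most bright transcripts do not change.

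Each array held 62976 spots, 58717 of them not controls, for 45598 probes, of which 2319 were printed more than once. Between 1 and 8 spots per array were non-uniform and were left out. Population outliers (272 to 363 per array) were kept, and none was saturated. Spots of a probe were averaged on the log2 scale, each array's 75th percentile was subtracted, and 19 probes without a usable spot on some array were left out. A probe was kept when it was well above background on all 3 arrays of at least 1 group (24254 probes). Per array 51.6% to 55.5% of probes were above background. The number of arrays, 3 per group, limits the precision, and the 95% interval of a difference between groups had a median half-width of 0.144 log2 units.

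The scanner files carry no gene symbols. Probe accessions were matched to a rat RefSeq table of gene symbols, used for names only, which named 21229 probes and left 24369 without a symbol. For a gene with several kept probes the brightest was used, which gave 20359 genes or transcripts, 10685 of them named. Among 2346 genes with several kept probes, called probes went in opposite directions for 23 genes between CCPB and DMSO, 19 between triclosan and CCPB, 4 between diclosan and CCPB and 0 in the other comparisons.

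All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of the package data.table) by group, and 6 pairwise contrasts were tested with moderated t-tests, two-sided, with Benjamini-Hochberg adjusted p under 0.05. The slide was found in the file headers and was not part of the model, and each comparison is also given with the slide as a fixed block. Confidence intervals are 95% and unadjusted. Where the dimmer group was not above background on any of its arrays, the fold difference is written "at least", as the brighter group's mean minus the dimmer group's, after each array of the dimmer group was raised to the lowest value that array held above background.

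Gene lists (21) were written before the data were examined: CAR and PXR, AhR, PPARalpha, NRF2 and p53 targets, cholesterol synthesis, fatty acid synthesis, the integrated stress response, endoplasmic reticulum chaperones, heat shock, glycolysis and HIF1 targets, oxidative phosphorylation, bile acid synthesis and transport, hepatocyte functions, conjugating enzymes, acute phase and inflammation, cell cycle, and markers of macrophages, stellate cells and fibroblasts, endothelial cells and cholangiocytes. Each list was tested against the other genes with camera at its preset inter-gene correlation of 0.01, adjusted over the 21 lists. An estimated correlation per list was an alternative. Members are counted by the test over all genes, and counts "over the list alone" adjust the p-values of the list's members only. With few arrays the estimated correlation is itself uncertain.

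Named genes followed a fixed rule. For each compound against DMSO they were the 8 largest rises and 8 largest falls among genes that passed, had a symbol, had all 3 arrays of 1 group beyond the other group's and had the brighter group above background on 3 arrays. For compounds against each other the number was 6 each way. From each list up to 4 members with the smallest p were taken, with a fixed set of liver genes given whatever their result. Of that set, Cyp2b1 had no named probe and Cyp7a1 was removed as dim. Some genes that met the rule are not reported here. A repeat of the rule on the slide-blocked fit was added after the values were seen.

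Similarity between compounds was given as overlaps of calls beside the overlap expected from the counts as if the comparisons were independent, and as the correlation and covariance of differences from DMSO, beside 20 simulations of unchanged groups that share the same DMSO arrays. No p-value was taken across genes.

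The alternatives were normexp background correction (offset 50), quantile normalization, median centring, the authors' value table, no filter on dim probes, a filter on all 12 arrays, the slide as a fixed or random block, the arrays of 1 slide only, the replicate number as a block with and without the slide, a fit of the compared groups only, an intensity trend with robust priors, the mean of all probes of a gene, a 2-fold minimum, and each array left out in turn. The files have no mean spot signal, so normexp used the median spot signal with the median local background. Added after the data were seen were the array column with and without the slide, population outliers left out, and the slide block with an estimated correlation.

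The model was tested on simulated data with 20359 genes and 100 changed genes at each of 2 sizes. For triclosan against DMSO it recovered 73% of changes of 0.5 log2 units and 93% of changes of 1, with 7 false calls. For CCPB against DMSO it recovered 79% and 91% with 11 false calls, and with the slide block 45% and 77% with 12. When a slide shift was simulated, the fit by group made 4139 false calls and the slide-blocked fit 6, with 38% and 82% recovered. Raw image files were not analysed here.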

Results

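Transcripts of primary rat hepatocytes were measured on 12 one-colour microarrays after exposure to 3 related diphenyl ethers. The hepatocytes came from male Sprague Dawley rats and had been cryopreserved. They were cultured for 24 h and then exposed for 24 h to the vehicle DMSO or to 30 µM of triclosan, diclosan or 1-chloro-3-(4-chlorophenoxy) benzene (CCPB), with 3 arrays in each of the 4 groups. Triclosan, an antibacterial agent, carries 3 chlorine atoms and a phenolic hydroxyl group. Diclosan keeps the hydroxyl group and lacks 1 of those chlorine atoms, and CCPB has 2 chlorine atoms, no hydroxyl group and 1 chlorine atom meta rather than para to the ether oxygen. The labels describe each array as an independent experiment, so the p-values of single genes below rest on the spread between these experiments. The camera p-values of lists set member genes against other genes at a preset correlation. They do not measure how a list varies between experiments. The labels do not tell whether the replicates used different rats or lots of hepatocytes, so the p-values are not shown to reach beyond the cells used.

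Between 51.6% (triclosan replicate 2) and 55.5% (DMSO replicate 3) of the probes were well above background, and no spot was saturated. After the filter on dim probes 20359 genes or transcripts were tested, of which 10685 had a gene symbol. The arrays lay on 2 slides. Slide 1 held the 3 DMSO arrays, the 3 triclosan arrays and diclosan replicates 1 and 2, and slide 2 held diclosan replicate 3 and the 3 CCPB arrays. Component 1 took 40.6% of the variance and placed the slide 1 arrays between -14.9 and -6.14, diclosan replicate 3 at 12.9 and the CCPB arrays between 24.5 and 27.1. Diclosan replicates 1 and 2 differed by a median of 0.0657 log2 units per gene, and replicate 3 differed from them by 0.114 and 0.114. Triclosan and DMSO shared a slide. CCPB shared no slide with DMSO or triclosan, so its differences from them are also given with the slide as a fixed block, and that block rests on diclosan replicate 3 against diclosan replicates 1 and 2 alone.

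**Figure D1:**
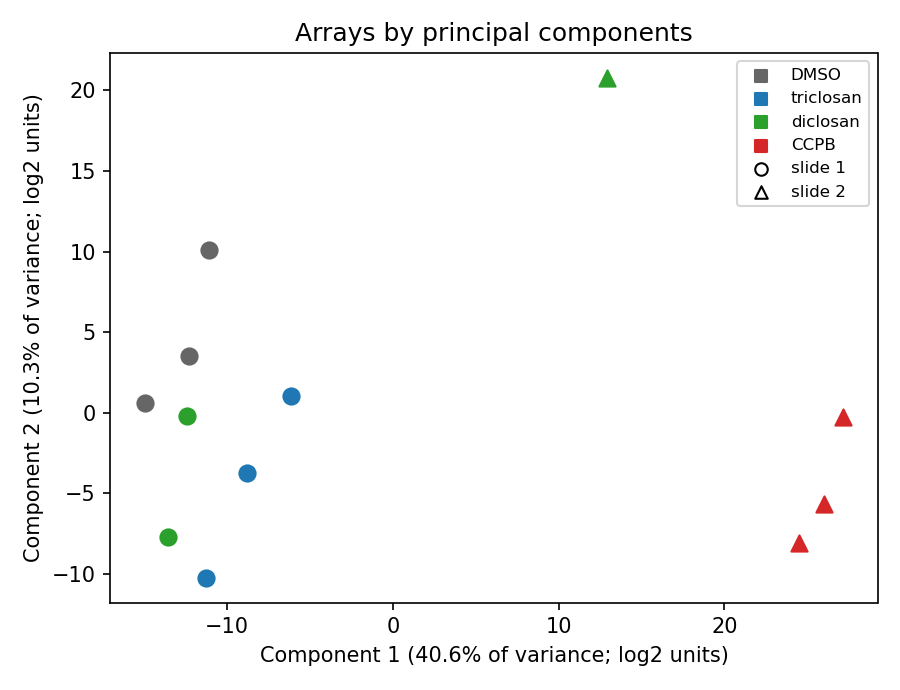
Principal components of the 12 arrays, computed on the log2 signal of the 20359 genes or transcripts after each array was set to its 75th percentile. Colours give the group and shapes give the slide. The CCPB arrays and diclosan replicate 3, the arrays of slide 2, lie on the right of component 1.

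Triclosan raised Nr0b2, a nuclear receptor corepressor that restrains bile acid synthesis, 4.27-fold over DMSO (log2 difference 2.09, 95% confidence interval 1.81 to 2.38, 3 arrays per group, limma adjusted p = 0.000309). Gdf15, a secreted stress-responsive cytokine, rose 1.78-fold (log2 difference 0.83, interval 0.62 to 1.04, adjusted p = 0.0175), and the transcriptional coregulator Cited4 rose 1.49-fold (0.58, interval 0.45 to 0.70, adjusted p = 0.00683). The glutathione transferase Gsta3 rose 1.19-fold (0.25, interval 0.17 to 0.33, adjusted p = 0.0496). Klf5, a zinc finger transcription factor, fell by 0.36 on the log2 scale (adjusted p = 0.00683), and the kinesin Kif26b fell by 0.27 (adjusted p = 0.0396). These 6 were the named genes among 13 changed transcripts, 9 higher and 4 lower, of which Nr0b2 alone reached 2-fold. Before adjustment 2359 transcripts had p under 0.05, where chance gives 1018. With the slide as a fixed block 46 changed (27 higher and 19 lower), among them all 13. Within slide 1 alone only Nr0b2 changed (adjusted p = 0.0162), and in a fit of these 6 arrays alone none did (Nr0b2 adjusted p = 0.0545).

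Apart from the fit of the triclosan and DMSO arrays alone, which called none, Nr0b2 was the only named gene called with triclosan under every setting. Leaving out any of the 6 arrays left 5 calls (without triclosan replicate 1 or 2) or 6 (without DMSO replicate 1, 2 or 3, or triclosan replicate 3). Gdf15 missed the threshold without DMSO replicate 2 (adjusted p = 0.0513), triclosan replicate 1 (0.0615) or triclosan replicate 2 (0.0833). Gsta3 (0.0832 to 0.169) and Kif26b (0.0615 to 0.169) missed it without any one array, and Klf5 missed it with the mean of all probes of the gene (0.164). With median centring Cited4 (0.125), Klf5 (0.125), Gsta3 (0.504) and Kif26b (0.402) missed it, and without the filter on dim probes so did Gdf15 (0.0698), Cited4 (0.0698), Klf5 (0.0698), Gsta3 (0.307) and Kif26b (0.285).

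The marker genes fixed beforehand and reported here did not pass the test with triclosan. Cyp1a1, the classic target of the aryl hydrocarbon receptor (AhR), differed by 0.27 (interval 0.054 to 0.49, adjusted p = 0.337). The xenobiotic-inducible Cyp3a23-3a1 differed by 0.098 (-0.050 to 0.25) and the peroxisome proliferator target Cyp4a1 by 0.044 (-0.042 to 0.13). The oxidative stress genes Hmox1 and Nqo1 differed by 0.17 (0.056 to 0.29) and 0.13 (0.041 to 0.22). Among stress genes, Ddit3 differed by 0.023 (-0.22 to 0.26), Trib3 by -0.010 (-0.16 to 0.14) and Fgf21 by 0.059 (-0.058 to 0.18). Cdkn1a, a p53 target, and Alb, which encodes albumin, differed by -0.00071 (-0.085 to 0.084) and -0.052 (-0.13 to 0.027).

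Cholesterol synthesis genes fell together with triclosan by small steps: the median of the 25 measured members was -0.096, 21 lay below 0 and the camera adjusted p was 1.38e-06. None of them passed the test over all genes, while 11 were lower when adjusted over the list alone. Acat2 had -0.21 (adjusted p = 0.106), Dhcr7 -0.17 and Lss -0.12. This was the only list that also passed with an estimated correlation (adjusted p = 0.032 with an estimated correlation, and 0.144 with the slide block besides).

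Conjugating enzymes rose as a list with triclosan (median 0.088 over 41 members, camera adjusted p = 4.52e-07, and 0.162 with an estimated correlation), with Gsta3 called and 2 members higher when adjusted over the list alone. Targets of the xenobiotic receptors CAR and PXR also rose (median 0.086 over 23, adjusted p = 0.000138, and 0.339 with an estimated correlation), with 0 called and 1 higher over the list alone, and Cyp2c6v1 and Cyp2b2 had 0.28 (adjusted p = 0.145) and 0.54 (0.259). Cell cycle genes fell (median -0.076 over 28, adjusted p = 0.0022), with 0 called and 1 lower over the list alone (adjusted p = 0.346 with an estimated correlation). PPARalpha targets (median 0.043, camera adjusted p = 0.0318, and 0.339 with an estimated correlation) and endoplasmic reticulum chaperones (0.043, 0.0232, and 0.581 with an estimated correlation) rose by small steps. The bile acid synthesis and transport list rose too (median 0.034, camera adjusted p = 0.0232, and 0.346 with an estimated correlation). Without the filter on dim probes none of the 3 passed (adjusted p = 0.329, 0.174 and 0.092). Chaperones were also lost with median centring (median 0.021, 0.185). PPARalpha targets were also lost with the slide (0.0538), the replicate number (0.0579) or both (0.0703) as blocks. In the bile acid list the mean was 0.184, far above the median, and Nr0b2 (2.09) was the call. Over the list alone 3 of its 18 members were higher and 1 lower.

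Without triclosan replicate 1 only 3 of the 7 list calls remained, and the adjusted p was 0.149 for cell cycle genes, 0.257 for chaperones, 0.0713 for the bile acid list and 0.0693 for PPARalpha targets. PPARalpha targets were also lost without DMSO replicate 1 (0.0535), DMSO replicate 3 (0.0531) or triclosan replicate 3 (0.135), and the bile acid list without DMSO replicate 1 (0.112) or 3 (0.0576). Of the 14 lists that did not pass, the integrated stress response had a median of -0.017 and a mean of 0.025 with Gdf15 as its 1 call. Medians lay below 0 and means above it for p53 targets (-0.010 and 0.010), oxidative phosphorylation (-0.0050 and 0.0030) and hepatocyte functions (-0.0080 and 0.033), and the reverse held for the acute phase list (0.0060 and -0.0030), all 5 with the test pointing up. Markers of macrophages (0.029), stellate cells and fibroblasts (-0.097), endothelial cells (-0.040) and cholangiocytes (-0.11) did not pass.

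Diclosan raised Nr0b2 3.48-fold over DMSO (log2 difference 1.80, interval 1.52 to 2.08, 3 arrays per group, limma adjusted p = 0.00131; 1.88 with adjusted p = 0.00495 under the slide block) and Cited4 1.53-fold (0.62, interval 0.49 to 0.74, adjusted p = 0.00715; 0.63 and 0.0253). These were the only 2 of 20359 transcripts that changed, both upward. Gdf15 differed by 0.68 and did not pass (adjusted p = 0.0624), and Gsta3 by 0.23 (0.0734). Unadjusted p lay under 0.05 for 2152 transcripts. Cited4 was lost without diclosan replicate 1 (0.0585) or 2 (0.0665), which left 1 call each, and with median centring (0.142) or no filter on dim probes (0.0608), whereas Nr0b2 was called without any one array. With slide 1 alone (2 diclosan arrays) 0 transcripts passed by limma, 1892 having unadjusted p under 0.05 (Nr0b2 1.88, adjusted p = 0.0692), and a fit of the 6 arrays of these groups gave 0 as well (Nr0b2 adjusted p = 0.12).

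Among the fixed markers reported here none passed with diclosan. Cyp1a1 differed by 0.25 (interval 0.035 to 0.47, adjusted p = 0.406), Nqo1 by 0.16 (0.077 to 0.25, adjusted p = 0.238) and Hmox1 by 0.15 (0.034 to 0.26). Cyp3a23-3a1 (0.078), Cyp4a1 (0.0044), Ddit3 (0.0039), Trib3 (0.0073), Fgf21 (0.023), Cdkn1a (0.026) and Alb (-0.042) had intervals that held 0.

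Cholesterol synthesis genes fell with diclosan, with a median of -0.15 over 25 members (camera adjusted p = 6e-15, adjusted p = 0.00176 with an estimated correlation and 0.0104 with the slide block besides). None passed over all genes and 14 were lower when adjusted over the list alone, with Acat2 at -0.30 (adjusted p = 0.0624), Cyp51 at -0.26, Fdps at -0.21 and Lss at -0.17. Fatty acid synthesis genes fell as well (median -0.093 over 20, adjusted p = 3.73e-05, and 0.0454 with an estimated correlation), 4 of them lower over the list alone, such as the desaturase Fads1 (-0.23) and the acetyl-CoA synthetase Acss2 (-0.20). With the slide block the fatty acid median was -0.053 (adjusted p = 0.00139, and 0.0698 with an estimated correlation besides).

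The other list calls with diclosan were lost with an estimated correlation. Cell cycle genes fell (median -0.11, camera adjusted p = 9.64e-07, adjusted p = 0.139 with an estimated correlation) and conjugating enzymes rose (0.072, 4.98e-06, and 0.139 with an estimated correlation). Endoplasmic reticulum chaperones rose (0.066, 0.00103, and 0.361 with an estimated correlation) unless diclosan replicate 1 was left out (0.173), and CAR and PXR targets rose (0.061, 0.017, and 0.371 with an estimated correlation) unless DMSO replicate 1 was left out (0.277) or the array column was a block (0.0842, and 0.237 with the slide besides, both chosen after the data were seen). Macrophage markers rose (median 0.14 over 8, adjusted p = 0.00442, and 0.218 with an estimated correlation) with 0 called, C1qb having 0.59 (adjusted p = 0.323) and Tyrobp 0.51 (0.504). The 6 measured AhR targets rose by a median of 0.13 (0.0324, and 0.248 with an estimated correlation). They did not pass under the slide block (0.138), which in this comparison is the same fit as leaving out diclosan replicate 3. Nor did they pass without DMSO replicate 1 (0.058) or DMSO replicate 2 (0.0618). This rise was also lost with probes above background on all arrays (0.0696), on slide 1 alone (0.166) and with replicate and slide (0.144). The array column, chosen after the data were seen, ended it as well (0.0617, and 0.411 with the slide). Without the filter on dim probes the median turned to -0.027 (0.712). PPARalpha targets fell (-0.018, 0.0174, and 0.218 with an estimated correlation), but not under the slide block, again the fit without diclosan replicate 3 (0.0836), nor without DMSO replicate 3 (0.0553). They were also lost on slide 1 alone (0.106), with normexp (0.0942), with median centring (0.0615), with replicate and slide (0.159) and with slide and column (0.237).

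The bile acid list rose with diclosan by a median of 0.035 and a mean of 0.155 (camera adjusted p = 0.0445, and 0.361 with an estimated correlation), Nr0b2 being its 1 call. It was lost without DMSO replicate 1 (0.274), DMSO replicate 3 (0.0948), diclosan replicate 1 (0.172) or diclosan replicate 2 (0.0758). It was also lost without the filter on dim probes (0.0656), with the replicate block (0.0657), with the compared groups only (0.0713) and with the array column (0.0871). Under the slide block the integrated stress response (median 0.028, adjusted p = 0.00707) and heat shock genes (0.048, 0.0264) also rose, neither with an estimated correlation besides (0.347 for both). Markers of stellate cells and fibroblasts (-0.12), endothelial cells (median 0.016, mean -0.081) and cholangiocytes (0.031 and -0.15) did not pass, the test of the latter 2 pointing down, and p53 targets had a median of -0.0020 and a mean of 0.012 with the test pointing up.

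CCPB, the compound without the hydroxyl group, raised Nr0b2 4.75-fold over DMSO (log2 difference 2.25, interval 1.97 to 2.53, limma adjusted p = 1.24e-05) and 2.50 on the log2 scale under the slide block (adjusted p = 0.00364). Cyp2b2, a P450 induced through CAR, rose 3.56-fold (1.83, interval 1.47 to 2.20, adjusted p = 8.69e-05, slide block 1.98, adjusted p = 0.0135, and 0.0748 with slide and array column, a setting chosen after the data were seen). Pcp4l1 rose 2.53-fold (1.34, adjusted p = 4.59e-05, slide block 1.63, 0.00451), and so did Colq, the collagen tail of acetylcholinesterase, 2.40-fold (1.26, 0.00151, slide block 2.10, 0.0012), although it was above background on 1 of 3 DMSO arrays. Rassf9, a Ras association domain protein, fell by 1.63 on the log2 scale (adjusted p = 1.24e-05, slide block -1.69, 0.00451), and the phospholipid scramblase Plscr2 fell by 1.42 (3.98e-05, slide block -1.52, 0.00818). In all, 5757 transcripts changed, 2903 higher and 2854 lower, of which 3147 had a symbol and 106 and 87 reached 2-fold.

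The number of transcripts called with CCPB depended on the slide block. With the slide as a fixed block 704 transcripts changed (338 higher and 366 lower), 611 of them called in the same direction without the block, and 89.7% of the 5757 kept their sign. The median absolute difference was 0.130 log2 units without the block and 0.119 with it, while the median half-width of the 95% interval widened from 0.144 to 0.233. On data simulated without a slide shift the block cut the recovery of changes of 0.5 from 79% to 45%. With a slide shift simulated, the fit without the block made 4139 false calls and the blocked fit 6. Leaving out 1 array left between 3671 and 4000 calls, with 3742 without DMSO replicate 1, 3750 without DMSO replicate 2, 3813 without CCPB replicate 2 and 3671 without CCPB replicate 3. No slide held both groups, so no value within a slide exists.

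Several further genes among the largest CCPB differences passed without the slide block only, each given with its adjusted p without and with that block. The STRIPAK component Mob4 rose at least 1.95-fold (adjusted p = 0.0059, slide block 0.571), the chemokine receptor Ccr2 at least 1.48-fold (0.018; 0.685) and the apoptosis inhibitor Bcl2a1 at least 1.49-fold (0.000676; 0.0704). Cyp26b1, which degrades retinoic acid, was at least 2.38-fold lower (0.000832; 0.109), the ciliary protein Tekt1 at least 1.47-fold (0.0358; 0.58), the apoptosis promoter Bik at least 1.77-fold (0.00481; 0.302) and the tetraspanin Tspan11 at least 1.75-fold (0.0101; 0.0895). Mical1, an actin-oxidizing enzyme, fell by 1.44 (0.000288, slide block -1.09, 0.0659). The copper transporter Slc31a1 rose by 1.35 (adjusted p = 0.0281) and had -0.40 under the slide block (0.33). As fitted, with the dimmer group's values below background and the sizes therefore uncertain, the log2 differences without and with the block were 1.92 and 0.63 for Mob4 (SE 0.38 and 0.5), 1.76 and 0.68 for Ccr2 (SE 0.449 and 0.737), 1.73 and 1.71 for Bcl2a1 (SE 0.226 and 0.430), -2.64 and -2.29 for Cyp26b1 (SE 0.359 and 0.669), -1.52 and -1.05 for Tekt1 (SE 0.463 and 0.860), -1.44 and -1.07 for Bik (SE 0.274 and 0.499) and -1.42 and -2.02 for Tspan11 (SE 0.315 and 0.548), so that the SE widened for all 7. Ccr2 was lost without DMSO replicate 2 or 3 or CCPB replicate 1 or 3 (0.0513 to 0.06), Tekt1 without any DMSO array (0.0801 to 0.0842) and Slc31a1 without any one array (0.0599 to 0.0844).

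Genes chosen by the same rule from the slide block, after the values were seen, added the immediate early gene Egr1 (log2 difference 1.05, slide block 1.43, adjusted p = 0.0073), the acyl-CoA thioesterase Acot5 (1.17; 1.41, 0.00885), Pdk4, which shuts down pyruvate oxidation (1.11; 1.22, 0.0102), and C1h11orf86 (1.18; 1.14, 0.0306) to the rises. They added the PCNA-associated factor Pclaf (-1.27, slide block -2.10, adjusted p = 0.00534), Dnd1 (-1.33 under the block), the Fanconi anemia gene Fancb (-1.28), the chromatin remodelling subunit Smarcd3 (-1.26), Calhm5 (-1.25) and Iqgap3 (-1.25) to the falls.

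Of the fixed markers, Cyp3a23-3a1 rose with CCPB (0.48, interval 0.34 to 0.63, adjusted p = 0.000871, slide block 0.57, 0.0387), as did Cyp4a1 (0.32, 0.23 to 0.40, 0.000465, slide block 0.32, 0.0469) and Hmox1 (0.41, 0.30 to 0.53, 0.000543, slide block 0.44, 0.0451). Cyp1a1 fell by 0.31 (adjusted p = 0.0408, slide block -0.59, 0.0661), Ddit3 by 0.38 (0.0287; 0.328) and Fgf21 by 0.24 (0.00911; 0.302). Cyp1a1 (0.0535 to 0.122) and Ddit3 (0.0564 to 0.0885) were lost without any one array and without the filter on dim probes (0.112 and 0.0833), and Fgf21 with normexp (0.436). Nqo1 (0.034, interval -0.054 to 0.12), Trib3 (-0.19, -0.34 to -0.036, adjusted p = 0.0641), Cdkn1a (0.068, -0.016 to 0.15) and Alb (-0.027, -0.11 to 0.052) did not pass.

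**Figure D2:**
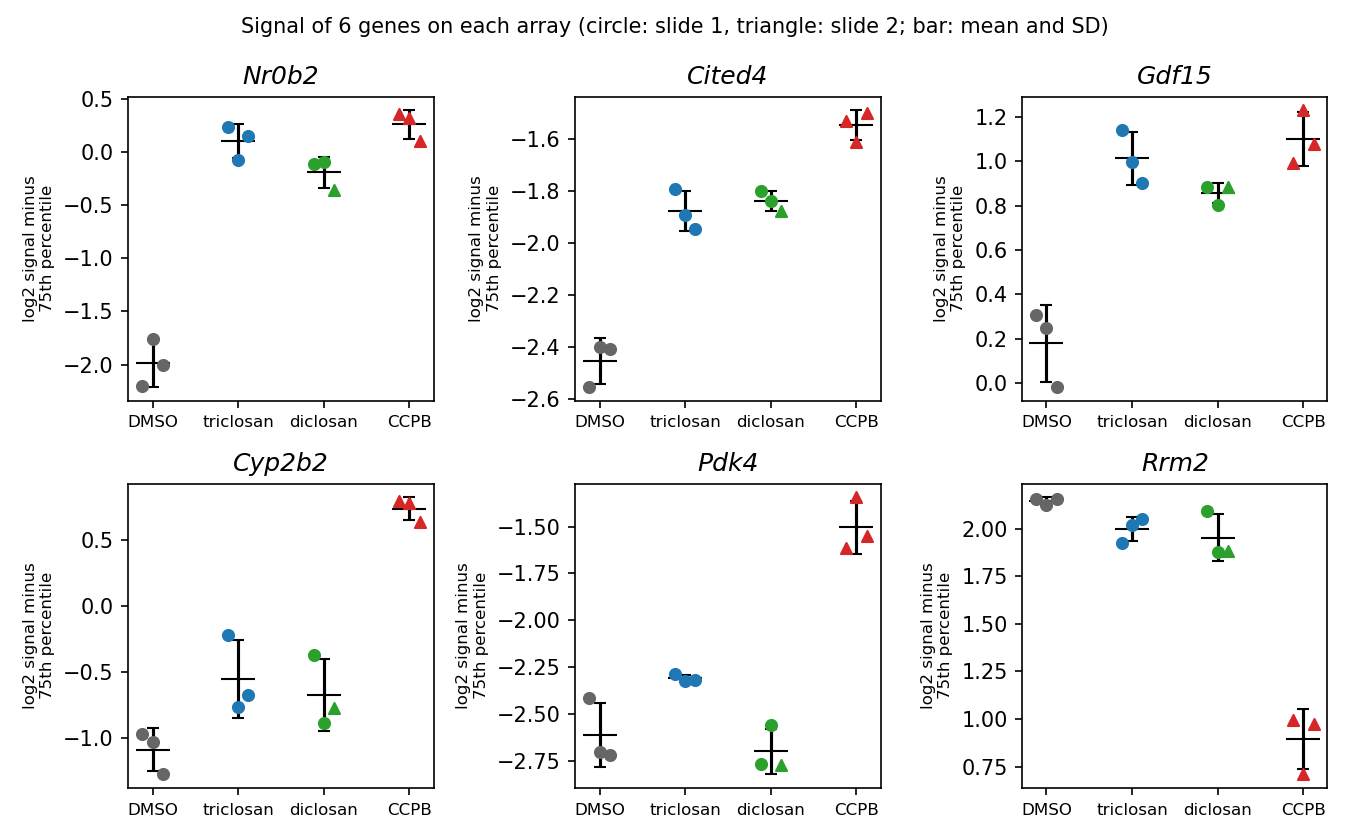
Signal of 6 genes on each array, as log2 signal minus the array's 75th percentile, so that 0 is the 75th percentile. Circles are arrays of slide 1 and triangles arrays of slide 2, and bars give the mean and SD of 3 arrays. Nr0b2 is higher with all 3 compounds, and Cyp2b2, Pdk4 and Rrm2 show their largest shift with CCPB.

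Cell cycle genes fell with CCPB: 25 of 28 measured members were lower (26 when adjusted over the list alone), with a median of -0.59 (camera adjusted p = 2.1e-18, and 0.014 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 fell by 1.25 (adjusted p = 1.77e-05, slide block -1.15, 0.0073), the replication licensing factors Mcm3 and Mcm7 by 0.67 and 0.57 (slide block -0.57 and -0.51) and the cyclin Ccne1 by 0.61 (slide block -0.55). Under the slide block the median was -0.56, with 14 lower (22 over the list alone, adjusted p = 0.0134 with an estimated correlation).

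Conjugating enzymes rose with CCPB, 28 of 41 called higher (30 over the list alone) with a median of 0.26 (camera adjusted p = 4.74e-13, and 0.023 with an estimated correlation, slide block 0.23, 8 higher). Gsta3 rose by 0.55 (slide block 0.50, adjusted p = 0.00581), the sulfotransferases Sult2a6 and Sult2b1 by 0.74 and 0.65 (0.85 and 0.70) and Gstm3 by 0.68 (0.87). PPARalpha targets rose, 23 of 46 higher and 1 lower (26 and 1 over the list alone; median 0.17, adjusted p = 4.53e-08, and 0.014 with an estimated correlation, slide block 0.22, 12 higher). Besides Pdk4, the mitochondrial carnitine palmitoyltransferases Cpt1a and Cpt2 rose by 0.44 and 0.37 (slide block 0.38 and 0.42) and the thioesterase Acot4 by 0.47 (0.48).

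Targets of CAR and PXR rose, 14 of 23 higher and 1 lower (16 and 1 over the list alone; median 0.30, camera adjusted p = 1.68e-07, slide block 0.23, 8 higher and 1 lower), but not with an estimated correlation (adjusted p = 0.0632 with an estimated correlation). Cyp2c6v1 rose by 0.92 (slide block 0.85, adjusted p = 0.0073), Cyp3a62 by 0.58 (0.47) and Cyp2c7 by 0.51 (0.44). The bile acid list rose, 10 of 18 higher and 1 lower (median 0.25, adjusted p = 1.24e-05, and 0.0611 with an estimated correlation, slide block 0.22, 6 higher), with the bile salt export pump Abcb11 up by 0.45 (0.40), the side-chain oxidase Acox2 by 0.81 (0.68) and the bile acid uptake carrier Slc10a1 by 0.53 (0.41). Hepatocyte functions rose, 18 of 41 higher and 2 lower (21 and 2 over the list alone; median 0.11, adjusted p = 0.000209, and 0.0632 with an estimated correlation, slide block 0.13, 5 higher), with the urea cycle enzymes Arg1, Asl and Ass1 up by 0.48, 0.35 and 0.34 and Apob by 0.37. Acute phase genes rose (7 of 19 higher, 1 under the slide block, median 0.076, adjusted p = 0.00917, and 0.267 with an estimated correlation), Cxcl1 by 0.93, Crp by 0.41 and Lbp by 0.24, none of the 3 under the slide block (0.0931, 0.0999 and 0.058).

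Chaperones of the endoplasmic reticulum fell with CCPB, 11 of 20 lower and 2 higher (median -0.14, camera adjusted p = 0.000209, and 0.266 with an estimated correlation). The members Sel1l, Derl3 and Sdf2l1 fell by 0.42, 0.62 and 0.39 in log2 units (slide block 0.134, 0.276 and 0.307 as adjusted p). The integrated stress response fell, 14 of 34 lower and 2 higher (median -0.13, adjusted p = 0.00129, and 0.267 with an estimated correlation), Aldh18a1, Psat1 and Ddit4 falling by 0.41, 0.32 and 0.42 (slide block 0.0626, 0.0649 and 0.175) while Gdf15 rose by 0.92 (slide block 0.88, adjusted p = 0.0338). Neither list passed under the slide block (0.0657 and 0.0783), with 0 chaperones called, and 0 lower and 2 higher in the integrated stress response. Oxidative phosphorylation rose (6 of 42 higher, 0 under the slide block, median 0.043, adjusted p = 0.0488, and 0.426 with an estimated correlation), but not with normexp (0.0558), quantile normalization (0.273) or median centring (0.223). It was also lost with no filter on dim probes (0.0691), probes above background on all arrays (0.0506), the compared groups only (0.0687) or the array column (0.114, and 0.189 with the slide), and without DMSO replicate 2 (0.0686), DMSO replicate 3 (0.0678) or CCPB replicate 3 (0.0991).

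Cholesterol synthesis genes did not pass with CCPB (6 of 25 higher and 4 lower, 0 called under the slide block, median 0.051), although Fdft1 and Hsd17b7 rose by 0.38 and 0.37 (slide block adjusted p = 0.684 and 0.179), and neither did fatty acid synthesis (4 of 20 higher, median 0.068, slide block 0.13 with 0 called, adjusted p = 0.00209, and 0.0338 with an estimated correlation besides), with Dgat2 up by 0.33 (slide block 0.0591). NRF2 targets did not pass either (7 of 26 higher and 2 lower, median 0.058, slide block 2 higher, adjusted p = 0.00311, but 0.16 with an estimated correlation besides), nor did p53 targets (7 of 19 lower, 0 under the slide block, median -0.063, adjusted p = 0.0678), of which Phlda3 fell by 0.52 and Aen fell by 0.23 (slide block 0.359 and 0.0835). For the 6 AhR targets the median was 0.031 and the mean -0.22 with the test pointing down, Aldh3a1 being at least 1.41-fold lower (adjusted p = 0.00123, slide block 0.103). Heat shock genes had a median of 0.023 and a mean of -0.011 with the test pointing up.

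Markers of other liver cell types did not pass as lists with CCPB. The macrophage median was 0.20 (2 of 8 higher, 1 under the slide block, among them the lipopolysaccharide receptor Cd14 at 0.30), and the endothelial median was 0.23 (2 of 5 higher, 0 under the slide block, adjusted p = 0.0583). Stellate cell and fibroblast markers had a median of -0.16 with 3 of 13 lower and 1 higher (1 and 1 under the slide block), the smooth muscle protein Tagln falling by 0.72 (slide block -0.59, adjusted p = 0.0371). Cholangiocyte markers had a median of 0.28 and a mean of -0.095 (4 of 7 higher and 2 lower, 0 called under the slide block, the test pointing up), with Ggt1 up by 0.43 and Epcam by 0.33 (slide block adjusted p = 0.0672 and 0.379).

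**Figure D3:**
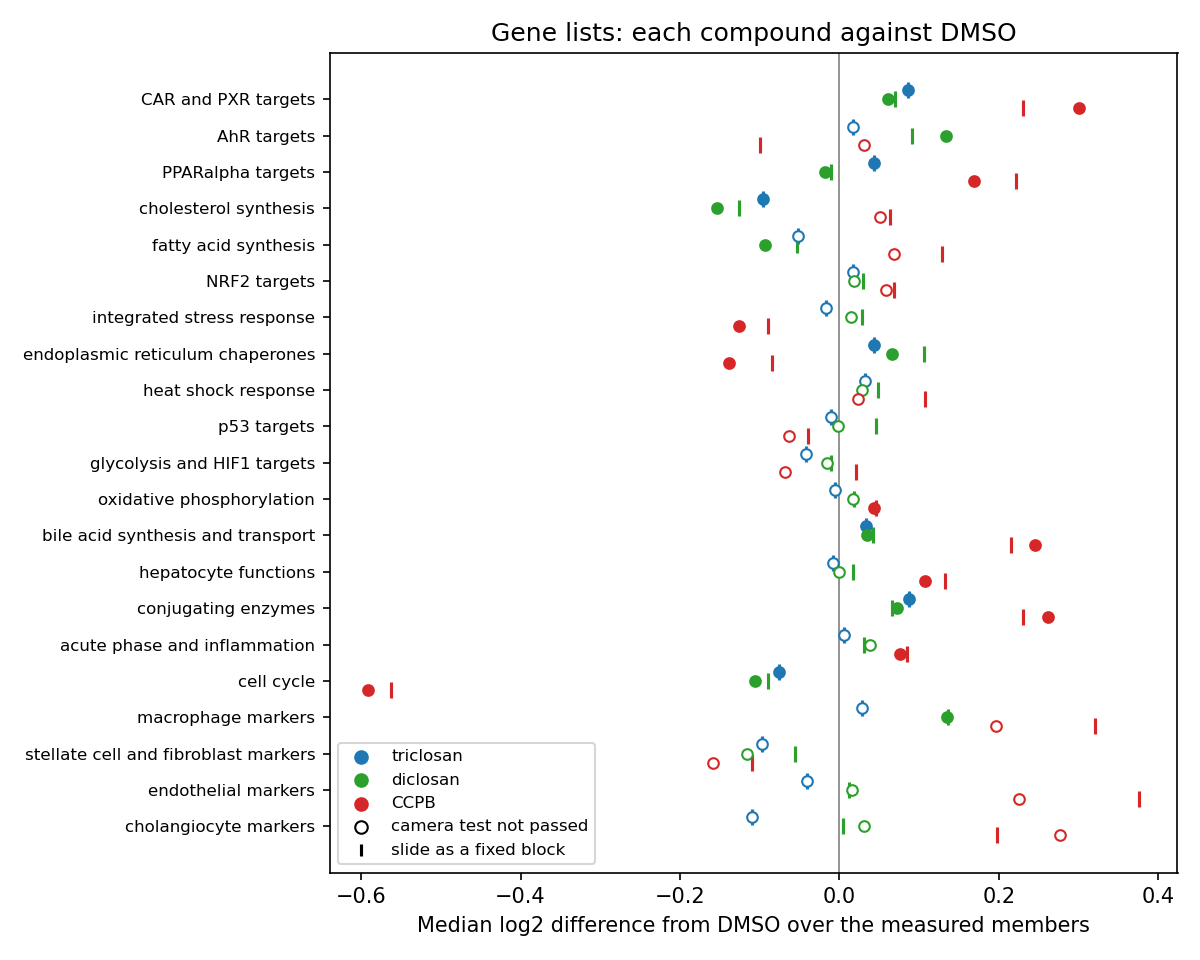
Median log2 difference from DMSO of the measured members of each of 21 fixed gene lists, for triclosan, diclosan and CCPB. Filled circles passed the camera test with the preset correlation at adjusted p under 0.05 and open circles did not. Short bars give the median with the slide as a fixed block. The cell cycle list lies furthest from 0 with CCPB.

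Triclosan and diclosan, which differ by 1 chlorine atom, gave no transcript that differed at the threshold (0 of 20359 by limma; 1391 had unadjusted p under 0.05, where chance gives 1018), and the median half-width of the 95% interval of a difference was 0.144 log2 units. For Nr0b2, triclosan minus diclosan was 0.30 (SE 0.126, interval 0.014 to 0.58, adjusted p = 0.714; 0.21 under the slide block). For Cited4 the difference was -0.039 (SE 0.056), for Gdf15 0.16 (SE 0.094) and for Gsta3 0.019 (SE 0.035), with adjusted p of 0.842 or more. Pdk4 differed by 0.39 (interval 0.18 to 0.61, adjusted p = 0.484), the stress transcription factor Atf3 by -0.24 (-0.32 to -0.15, 0.209) and the fatty acid elongase Elovl6 by 0.19 (0.090 to 0.29, 0.479). Cyp1a1 differed by 0.019 (-0.20 to 0.24), Cyp3a23-3a1 by 0.020 (-0.13 to 0.17), Cyp4a1 by 0.040 (-0.046 to 0.13), Hmox1 by 0.022 (-0.093 to 0.14) and Nqo1 by -0.035 (-0.12 to 0.052). Ddit3 (0.019), Trib3 (-0.017), Fgf21 (0.035), Cdkn1a (-0.027) and Alb (-0.0099) also had intervals that held 0. Intervals as wide as these leave open differences of a size that the test missed. The slide block gave 1 transcript, without a symbol, and is here the same fit as leaving out diclosan replicate 3. Leaving out diclosan replicate 1 or 2 gave 2 and 1, and the within-slide count was 0 (1449 unadjusted).

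PPARalpha targets were higher with triclosan than with diclosan as a list (median 0.052, camera adjusted p = 1.79e-08, and 0.0185 with an estimated correlation, slide block 0.046, 6.06e-05), with 0 members called. Cholesterol synthesis (0.048, 0.000224, and 0.0556 with an estimated correlation) and fatty acid synthesis (0.029, 0.00332, and 0.109 with an estimated correlation) were also higher as lists. The latter did not pass under the slide block, here the same fit as without diclosan replicate 3 (0.0804). Fatty acid synthesis was also lost on slide 1 alone (0.0861), with normexp (0.0552), with replicate and slide (0.0873) or with slide and column (0.066). Macrophage markers were lower (-0.13, 0.0288, and 0.522 with an estimated correlation), C1qb differing by -0.57 (interval -0.97 to -0.17), but not without triclosan replicate 1 (0.0706), triclosan replicate 2 (0.247) or diclosan replicate 2 (0.283). They were also lost on slide 1 alone (0.054), with the replicate block (0.0533) and with the array column (0.115, and 0.189 with the slide). Under the slide block the integrated stress response (median -0.042) and chaperones (-0.044) were also lower (adjusted p = 0.0225 for both), but not with an estimated correlation besides (0.776 for both). Median, mean and test differed in sign for heat shock (-0.0090 and -0.0010, up), p53 targets (0 and -0.0020, up), glycolysis (-0.0070 and 0.012, down), stellate markers (-0.030 and 0.074, down) and endothelial markers (0.051 and 0.0040, down), none of which passed.

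Triclosan and CCPB, which differ by the hydroxyl group, 1 chlorine atom and the position of another, differed in 4172 transcripts, 1930 higher and 2242 lower with triclosan (2244 with a symbol; 39 and 76 by at least 2-fold). Cyp2b2 was 2.45-fold lower with triclosan (log2 difference -1.29, interval -1.66 to -0.93, limma adjusted p = 0.00106, slide block -1.44, 0.0623) and Pclaf 2.67-fold higher (1.42, 0.93 to 1.90, 0.00272, slide block 2.25, 0.0135). Cyp1a1 was higher by 0.58 (0.36 to 0.80, 0.00425, slide block 0.87, 0.0335). With the slide as a fixed block 287 differed (156 higher and 131 lower), 234 of them in both fits, and 88.8% of the 4172 kept their sign. With median centring 35.7% of 2387 calls were higher with triclosan, against 46.3% of 4172. Leaving out 1 array left 2111 to 2897 calls, with 2289 without triclosan replicate 2, 2155 without triclosan replicate 3, and 2339, 2111 and 2314 without CCPB replicates 1, 2 and 3.

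Near background, triclosan gave at least 1.62-fold higher Cyp26b1 (adjusted p = 0.0047), 1.57-fold higher Tspan11 (0.0229) and 1.69-fold higher mitotic kinase Pbk (0.00847), and at least 1.71-fold lower peptide hormone Pyy (0.0479), 1.78-fold lower Mob4 (0.0149) and 1.27-fold lower Pbp2 (0.0214). The centrosomal gene Cep112 (1.30, above background on 2 of 3 CCPB arrays) and the replication factor Cdc6 (1.17) were higher, and Id3 (-1.63) and Slc31a1 (-1.34) lower. None of these 10 passed under the slide block (adjusted p of 0.148 to 0.821), where Id3 had 0.30 and Slc31a1 0.42. Id3 (0.0639 to 0.0994) and Slc31a1 (0.0764 to 0.106) were lost without any one array. Pbp2 was lost without triclosan replicate 1 or 3 or any CCPB array (0.0547 to 0.062), Pyy without triclosan replicate 1 or 2 or any CCPB array (0.0785 to 0.126), Tspan11 without triclosan replicate 2 or 3 or CCPB replicate 2 or 3 (0.061 to 0.0758) and Mob4 without triclosan replicate 3 (0.0533). Genes chosen from the slide block after the values were seen were the kinetochore genes Cenpt (1.13, slide block 1.17, adjusted p = 0.0119) and Ndc80 (0.80; 1.11, 0.0385), the steroidogenic Cyp17a1 (-0.90; -1.01, 0.0119) and Pcp4l1 (-1.01; -1.30, 0.0214).

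Further fixed markers were lower with triclosan than with CCPB, Cyp3a23-3a1 by -0.39 (adjusted p = 0.00466, slide block 0.101), Cyp4a1 by -0.27 (0.00197; 0.109) and Hmox1 by -0.24 (0.0127; 0.228). Fgf21 was higher by 0.30 (0.00509; 0.233) and Ddit3 by 0.40 (0.0301; 0.355), the latter lost without any CCPB array (0.0607 to 0.0917). Nqo1 (0.095, interval 0.0077 to 0.18), Trib3 (0.18, 0.026 to 0.33), Cdkn1a (-0.069, -0.15 to 0.015) and Alb (-0.025, -0.10 to 0.054) did not pass.

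Cell cycle genes were higher with triclosan than with CCPB, 23 of 28 called (27 over the list alone; median 0.53, camera adjusted p = 9.09e-20, and 0.0136 with an estimated correlation, slide block 0.50, 9 called). PPARalpha targets were lower (19 of 46 lower and 2 higher, median -0.14, and 0.0136 with an estimated correlation, slide block -0.19, 4 lower), and so were, each with its adjusted p with an estimated correlation, cholesterol synthesis (10 of 25, -0.10; 0.0323), fatty acid synthesis (8 of 20, -0.12; 0.0447), hepatocyte functions (13 of 41 lower and 1 higher, -0.084; 0.0447) and conjugating enzymes (19 of 41, -0.16; 0.0417). Members lower under the slide block were 1 cholesterol synthesis, 0 fatty acid synthesis, 1 hepatocyte function and 3 conjugating enzyme genes (medians -0.13, -0.14, -0.12 and -0.13). With the slide block and an estimated correlation together, conjugating enzymes had an adjusted p of 0.0691. Another 8 lists passed with the preset correlation only and are given with the adjusted p of the estimated one. CAR and PXR targets (-0.24, adjusted p = 0.0809 with an estimated correlation), the bile acid list (-0.17; 0.07), the acute phase list (-0.067; 0.177), oxidative phosphorylation (-0.056; 0.462) and endothelial markers (-0.28; 0.0809) were lower. Chaperones (0.19, and 0.0875 with an estimated correlation), the integrated stress response (0.089; 0.177, and 0.0519 under the slide block) and p53 targets (0.082; 0.0875, and 0.12 under the slide block) were higher. AhR targets were also higher under the slide block (median 0.19, adjusted p = 0.00984, and 0.0691 with an estimated correlation besides) and NRF2 targets lower (-0.079, 0.00984, and 0.195 with an estimated correlation besides). Oxidative phosphorylation was lost without triclosan replicate 2 (0.146), triclosan replicate 3 (0.0656) or CCPB replicate 3 (0.107). It was also lost with normexp (0.129), quantile normalization (0.482), median centring (0.157), the compared groups only (0.1) and the array column (0.126, and 0.277 with the slide). With normexp p53 targets (0.0548) and endothelial markers (0.0674) were lost, the latter also without the filter on dim probes (0.108). With replicate and slide both were lost (0.261 and 0.0877).

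Diclosan and CCPB each carry 2 chlorine atoms and differ by the hydroxyl group and the position of 1 chlorine atom. They differed in 2925 transcripts, 1649 higher and 1276 lower with diclosan (1755 with a symbol; 37 and 17 by at least 2-fold). Rassf9 was 2.69-fold higher with diclosan (log2 difference 1.43, interval 1.24 to 1.62, limma adjusted p = 4.43e-05, slide block 1.47, 0.00171) and Cyp2b2 2.67-fold lower (-1.42, -1.78 to -1.05, 0.000565, slide block -1.51, 0.0105). Pdk4 (-1.20, slide block -1.27), Acot5 (-1.04; -1.20), Pcp4l1 (-1.31; -1.50) and Colq (-1.33; -1.89, above background on 1 of 3 diclosan arrays) were lower. Pclaf (1.34, slide block 1.90, adjusted p = 0.00273), Cdc6 (1.27; 1.47, 0.0413) and Espl1, the protease that separates sister chromatids (1.22; 1.03, 0.0335), were higher. Cyp26b1 was at least 2.21-fold higher (0.0018, slide block 0.0417) and the aldehyde dehydrogenase Aldh3a1, an AhR target, at least 1.75-fold higher (0.000557; 0.0151). The dendritic cell lectin Clec9a was at least 1.60-fold lower (0.0289, slide block 0.159) and lost without diclosan replicate 1 (0.108) or CCPB replicate 2 (0.0926) or 3 (0.0911).

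With the slide as a fixed block 1007 transcripts differed between diclosan and CCPB (510 higher and 497 lower), 844 of them in both fits, and 100% of the 2925 kept their sign. Under that block the difference is diclosan replicate 3 alone minus the CCPB mean. The difference without the block holds the same array, so the kept signs are no independent support. Slide 2 alone, with 1 diclosan array, gave 0 by limma (3463 with unadjusted p under 0.05), and a fit of these 6 arrays alone gave 1235. Without diclosan replicate 3 the count was 5444, but diclosan and CCPB then shared no slide, so compound and slide cannot be told apart in that count. It was 1651 and 1806 without diclosan replicates 1 and 2 and 1798 and 1864 without CCPB replicates 2 and 3. Cyp1a1 was higher with diclosan by 0.57 (0.00512, slide block 0.75, 0.00884), and Cyp3a23-3a1 (-0.41, slide block adjusted p = 0.0262), Cyp4a1 (-0.31; 0.0157) and Hmox1 (-0.26; 0.0719) were lower. Fgf21 (0.26; 0.117) and Ddit3 (0.38; 0.203) were higher, Ddit3 being lost without any one array (0.0625 to 0.124). Nqo1 (0.13, interval 0.043 to 0.22), Trib3 (0.20, 0.044 to 0.35), Cdkn1a (-0.043, -0.13 to 0.042) and Alb (-0.015, -0.094 to 0.064) did not pass.

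Cell cycle genes were higher with diclosan than with CCPB, 22 of 28 called (24 over the list alone; median 0.50, 0.00834 with an estimated correlation, slide block 0.50, 17 called). PPARalpha targets were lower (23 of 46 lower and 2 higher, 30 and 2 over the list alone; median -0.19, 0.00286 with an estimated correlation, slide block -0.24, 22 lower), as were, each with its adjusted p with an estimated correlation, cholesterol synthesis (13 of 25, -0.15; 0.00595), fatty acid synthesis (10 of 20, -0.18; 0.0114), conjugating enzymes (21 of 41, -0.18; 0.0166), hepatocyte functions (13 of 41, -0.12; 0.0166), the bile acid list (7 of 18 lower and 1 higher, -0.22; 0.037) and CAR and PXR targets (14 of 23 lower and 1 higher, -0.24; 0.0433, and 0.0741 with the slide block besides). Under the slide block 7 cholesterol synthesis, 8 fatty acid synthesis, 7 conjugating enzyme, 10 hepatocyte function and 6 bile acid genes were lower, and 9 CAR and PXR targets were lower and 1 higher. Chaperones (16 of 20, 0.20, adjusted p = 0.0672 with an estimated correlation) and the integrated stress response (14 of 34, 0.15; 0.0992) were higher with the preset correlation only, as were p53 targets (7 of 19, 0.058; 0.0672, and 0.0527 under the slide block). With the slide block 3 chaperones were higher, as were 3 integrated stress response genes with 1 lower and 1 p53 target with 1 lower. The acute phase list (-0.087, adjusted p = 0.215 with an estimated correlation) and endothelial markers (1 of 5, 0 under the slide block, -0.18; 0.0672, and 0.0602 without diclosan replicate 3) were lower. The acute phase list was lost with quantile normalization (0.0807), and endothelial markers without the filter on dim probes (0.435). With replicate and slide p53 targets and endothelial markers were lost (0.133 and 0.105), as were p53 targets on slide 2 alone (0.0782). AhR targets were also higher under the slide block (median 0.19, adjusted p = 0.00613) and NRF2 targets (-0.068, 0.0044) and oxidative phosphorylation (-0.034, 0.0254) lower. None of the 3 passed with an estimated correlation besides (0.0529, 0.134 and 0.526). Median, mean and test differed in sign for heat shock (0.029 and 0.025, down) and stellate markers (0.046 and -0.025, up), neither of which passed.

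Nr0b2 and Cited4 rose with all 3 compounds. The genes that triclosan and CCPB changed in the same direction numbered 10 (8 higher and 2 lower), against 1.28 and 0.561 expected from the counts of calls for the higher and lower ones, and included Gdf15, Gsta3, Klf5 and Kif26b. Triclosan and diclosan shared 2 higher genes against 0.000884 expected, and diclosan and CCPB shared 2 against 0.285. Those expectations treat the comparisons as independent, although all share the 3 DMSO arrays. In 20 simulations with no effect and shared DMSO arrays the mean overlap was 0 for triclosan and diclosan, 0 for triclosan and CCPB and 0.05 for diclosan and CCPB. Unchanged groups give few calls to share. These overlaps therefore cannot show how many shared calls the common DMSO arrays produce where many transcripts are called. Over all genes the differences from DMSO correlated at 0.521 for triclosan and diclosan, 0.42 for triclosan and CCPB and 0.548 for diclosan and CCPB. The same simulations gave mean correlations of 0.496, 0.499 and 0.498. The covariance was above its simulated value by 0.00367 for triclosan and diclosan, 0.00996 for triclosan and CCPB and 0.0152 for diclosan and CCPB, a pair that includes the shared slide 2.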

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

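Over all alternatives 2587 list results kept their side of the threshold, 172 lost it, 97 gained it and none that passed reversed the direction of the camera test. Where a test passed, medians changed sign only for AhR targets: to -0.027 with diclosan and -0.21 with CCPB without the filter on dim probes, and to -0.16 with CCPB with slide and column. Counts of changed transcripts follow, main counts being 13 for triclosan, 2 for diclosan and 5757 for CCPB against DMSO, 0 for triclosan against diclosan, 4172 for triclosan against CCPB and 2925 for diclosan against CCPB; the cause was not tested except where the alternative itself shows it (fewer arrays, more or fewer probes, a stricter threshold). The arrays of a single slide give no value for CCPB against DMSO or triclosan.

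Normexp gave 20 calls for triclosan and 9 for diclosan against DMSO, and quantile normalization 26 for triclosan. Median centring gave 2 and 1 for triclosan and diclosan, 3316 for CCPB, 2387 for triclosan against CCPB and 1368 for diclosan against CCPB. Without a filter on dim probes the counts were 1, 1, 2805, 1398 and 1273 in that order, and with probes above background on all arrays 33 for triclosan and 10 for diclosan. The slide as a fixed block gave 46 for triclosan, 704 for CCPB, 1 for triclosan against diclosan, 287 for triclosan against CCPB and 1007 for diclosan against CCPB, and as a random block 40 for triclosan and 1830, 877 and 1730 for the 3 comparisons with CCPB. A single slide gave 1 for triclosan, 0 for diclosan and 0 for diclosan against CCPB. Only the groups compared gave 0 for triclosan, 0 for diclosan and 1235 for diclosan against CCPB. The intensity trend with robust priors gave 130 for triclosan, 48 for diclosan and 4 between them. At least 2-fold changes numbered 1, 1, 193, 115 and 54.

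The replicate numbers did not pair the arrays: same-number correlations ran from -0.165 to 0.117, 1 of 18 pairs over 0.1, and 2 of 12 arrays matched their own number best. The replicate block gave 26 for triclosan and 6 for diclosan, and with the slide 0 for diclosan and 300, 12 and 569 for the comparisons with CCPB. Leaving out 1 array gave 5 to 6 for triclosan, 1 to 3 for diclosan, 3671 to 4000 for CCPB, 0 to 2 for triclosan against diclosan, 2111 to 2897 for triclosan against CCPB and 1651 to 5444 for diclosan against CCPB. The 5444 came without diclosan replicate 3, which left diclosan and CCPB on separate slides. Alternatives chosen after seeing the data gave 5 for triclosan with the array column as a block, and with slide and column 0 for diclosan and 152, 5 and 603 for the comparisons with CCPB.

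With an estimated correlation 1, 2 and 3 lists shifted with triclosan, diclosan and CCPB, and 1, 6 and 8 for triclosan against diclosan, triclosan against CCPB and diclosan against CCPB; with the slide block as well (chosen after seeing the data) the counts were 0, 1, 6, 1, 5 and 7. Leaving out 1 array shifted 3 to 10 lists with triclosan. Genes shared by triclosan and diclosan (2) numbered 1 with median centring, 1 without the filter, 4 with all arrays above background, 4 with the replicate block and 0 with replicate and slide. Genes shared by triclosan and CCPB (10) numbered 19 with normexp, 20 with quantile normalization, 2 with median centring, 1 without the filter, 28 with all arrays above background, 29 and 28 with the slide as a fixed and random block and 23 with the replicate block. Genes shared by diclosan and CCPB (2) numbered 8 with normexp, 1 with median centring, 1 without the filter, 7 with all arrays above background, 6 with the replicate block and 0 with replicate and slide.

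Slc31a1 reversed between CCPB and DMSO (-0.40 with the slide, -0.46 with replicate and slide, -0.12 with slide and column) and between triclosan and CCPB (0.42, 0.47 and 0.13), as did Id3 between triclosan and CCPB (0.30, 0.60 and 0.16); the cause was not tested.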

Other observations

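Genes of mitosis and of DNA replication, in lists written after the data were seen, both fell with CCPB. These lists are not independent of the fixed cell cycle list, which had shown the fall first: 14 mitosis and 11 replication genes belong to it, 25 of its 28 measured members. Of 33 measured mitosis genes 27 were lower than with DMSO (30 over the list alone; median -0.72, camera adjusted p = 1.81e-17, and 0.0188 with an estimated correlation), and under the slide block the median was -0.76 with 16 lower. Of 34 DNA replication genes 24 were lower and 1 higher (median -0.34, adjusted p = 4.1e-14, and 0.0116 with an estimated correlation; slide block -0.30). Without the shared members 13 of 19 mitosis genes were lower (median -0.69, slide block -0.78; adjusted p = 0.00856 with an estimated correlation) and 16 of 23 replication genes were lower and 1 higher (-0.32, slide block -0.26; 0.00305 with an estimated correlation), adjusted over these 2 tests. With diclosan the medians were -0.099 for mitosis (0.000312) and -0.043 for replication (0.00309), and with triclosan -0.070 for mitosis (0.0296), all lost with an estimated correlation (adjusted p = 0.246, 0.246 and 0.736 with an estimated correlation). The mitosis call with triclosan was also lost under the slide block (camera adjusted p = 0.056).

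Immediate early genes rose slightly with diclosan (median 0.093, camera adjusted p = 0.000312; adjusted p = 0.246 with an estimated correlation) and ribosomal protein genes fell (median -0.034, 0.00384; 0.405 with an estimated correlation). Circadian clock genes also fell with diclosan (median -0.056, 0.046; 0.246 with an estimated correlation), but not under the slide block (0.455). With CCPB neither passed (0.088 and -0.022, both with adjusted p = 0.248), although under the slide block immediate early genes did (0.111, adjusted p = 0.00708; 0.28 with an estimated correlation besides). Circadian clock genes (median -0.063, 1 of 14 higher and 3 lower) and retinoic acid genes (-0.0050) did not pass with CCPB either, with Rarb higher (0.37, adjusted p = 0.000602, slide block 0.45, 0.0233) and Cyp26b1 lower (not called under the slide block).

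All tests that follow were chosen after the results they bear on had been seen, apart from the splits of arrays and the shift of diclosan replicate 3. With 10 splits of 6 arrays into 3 and 3, too few for a share under 0.05, the real split and the highest other one called 13 and 0 transcripts for triclosan against DMSO (1 split reached the real count, the real one), 2 and 1 for diclosan (1), 5757 and 0 for CCPB (1), 0 and 0 for triclosan against diclosan (10), 4172 and 1 for triclosan against CCPB (1) and 2925 and 0 for diclosan against CCPB (1).

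The many calls between CCPB and DMSO could come from the slide rather than the compound, since CCPB and DMSO shared none. A slide shift that is equal on all arrays of a slide is argued against as the whole cause. With the slide as a fixed block 704 transcripts were called, where at most 12 false calls arose in simulation. The block leans on 3 diclosan arrays, of which only replicate 3 shared the slide of CCPB, so the shift has no replicate there. The slide is therefore not excluded as the whole cause where its effect differs between arrays. As part of the cause it fits: over the 5757 called transcripts diclosan replicate 3 lay toward CCPB by a median of 0.079 against the other diclosan arrays, while the triclosan arrays gave -0.012 to 0.007, and the median CCPB difference was 0.284. That shift went toward CCPB in 73.3% of the called transcripts, so the count of 5757 may hold many that CCPB did not change. No array of CCPB beside DMSO on a slide exists to separate the remainder.

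The rise of Nr0b2 with all 3 compounds could reflect the slide or activation of FXR, the bile acid receptor that drives it. The slide is excluded for triclosan, where slide 1 alone gave 2.09 (interval 1.80 to 2.39). For diclosan, replicates 1 and 2 on slide 1 had log2 signals of -0.116 and -0.097. The DMSO arrays of that slide had -2.204 to -1.759. These values argue against the slide for diclosan, although Nr0b2 did not pass on slide 1 alone (limma adjusted p = 0.0692). The rise with CCPB has no such test, since CCPB and DMSO shared no slide. FXR activation by triclosan and diclosan that also moves its other listed targets stays open: 15 of 22 targets with triclosan and 17 of 22 with diclosan moved as FXR drives them, with 0 called, the lower of the signed medians was 0.022 (0.0090 to 0.037 over resampled genes), and neither passed the camera test (adjusted p = 0.154 for both). For CCPB the targets passed that test (adjusted p = 0.00822), 8 being called as FXR drives them and 2 against, with a median of 0.069 (0.018 to 0.15, slide block 0.114). Hepatocyte functions rose by 0.107 too (slide block 0.132), so FXR activation and a broader rise cannot be told apart. Activation seen at Nr0b2 alone stays open as well, since Cyp7a1 was on the array but removed as dim, and Cyp8b1, Slc51a and Slc51b were not among the genes tested.

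The fall of cell cycle genes with CCPB could come from the slide, from loss of dividing cells other than hepatocytes, or from fewer hepatocytes in cycle. With the slide block the median was -0.563 (-0.73 to -0.465 over resampled genes) against -0.591 without it. This argues against the slide, within the reach of a block that rests on diclosan replicate 3. A fall of macrophage or endothelial markers as large as that of the cell cycle list was not seen. The lower of their medians was 0.196, for macrophages (8 markers, 0.051 to 0.299 over resampled genes), and the endothelial one was 0.225 (5 markers, 0.193 to 0.467). Such ranges carry no spread between arrays, and steady markers cannot exclude the loss of a small dividing part of these cells. Stellate cell and fibroblast markers fell by less than the cell cycle list, with a median of -0.158 (13 markers, -0.276 to -0.043 over resampled genes). A partial loss remains possible at that value, and the loss of a dividing part of these cells is not excluded either. Cell counts or staining would be needed to test the hypothesis that fewer hepatocytes entered the cycle.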
